A study of Homo sapiens with 2 samples.

How the data were processed

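Huh7 cells were grown in DMEM with serum and 1 culture received apigenin at 10 µM for 24 h, and total RNA was taken with Trizol and labelled with Hy5, per the labels. Each culture gave 1 array, so the control and apigenin groups held 1 sample each, and nothing in the labels gives a further culture. The deposited scanner intensity of each spot is, per the file headers, the brightness at 635 nm of the pixels in the spot (foreground) and around it (local background), neither subtracted nor normalized. The feature extraction software is not given in the sources used here. Laser power was 100 on both arrays and the detector gain was 33 on the control array and 34 on the apigenin array, per the file headers. Each array had 3200 spots in 32 blocks, of which 2019 were miRNA probes with 1 spot each, 925 were blank, 16 were spike-in controls and 24 negative controls, which read 33.6 (SD 2.63) and 32.9 (SD 2.25) units. 94 further spots named S-Probe and 122 other spots were not part of the comparison. One miRNA spot marked as bad on the control array was left out, which left 2018, and 15 probes that name several miRNAs were kept under their joint name.

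The deposited value table gave intensity for 316 miRNAs on the control array and 411 on the apigenin array, with 260 on both and a median of 25.0 on each array. Set against the scanner foreground, its values had a Pearson r of 0.921 and 0.914 across miRNAs on the log scale, which are not independent replicates, and lay about 3.44 and 3.88 times above the foreground less the blank level. How the table's background and scale were made is not given in the sources used here. Because the median was set over lists of different length, its ratios were also given with their median set to 0.

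For the ratios, the foreground median and local background median were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, control spots were then left out, and the 2 arrays were quantile normalized over the miRNA probes. A miRNA was called detected where foreground less local background exceeded the mean plus 2 SD of the blank spots, after the highest and lowest 5% of these were left out, which put the limit at 11.8 units on the control array and 10.7 on the apigenin array. Ratios are log2 of apigenin over control for the 106 miRNAs detected on both arrays, and 103 were detected on the apigenin array only and 98 on the control array only. A miRNA detected on 1 array has only a bound, its level there over the higher of the other array's lowest detected level and its own level on that array. No test was possible with 1 array per group, so differences are described by size at 2-fold and 1.5-fold. The number of arrays limits the precision, and the spike-in spots give a spread between spots, not between cultures. The tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the plots with matplotlib 3.10.9.

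The local background was high beside bright spots, possibly from light of the spot itself. On the spike-in spots its median was 56.7% of the foreground on the control array and 67.2% on the apigenin array, and beside miR-4454 it was 23057 and 25383 units under a foreground of 43012 and 42422 units. Quantile normalization also turns the ratio of a bright miRNA into a change of rank, and 3 of the 10 brightest and 6 of the 106 had a ratio of exactly 0. The setting chosen before the data were examined was kept, and values with the level of the blank spots as background, with detection on the foreground (limits 36.5 and 36.6 units), were added after seeing the data. These were quantile normalized, left unscaled, or scaled so that the spike-in spots had a mean log2 ratio of 0, which is called the spike-in scale. A blank-spot background with no scaling gave the spike-in spots a mean log2 ratio of 0.23 (SE 0.077 over 16 spots). This SE covers repeat spots of 2 controls that differed, at 0.08 (SE 0.045) and 0.37 (SE 0.13), so scaling on each control alone was added and moves every value on the spike-in scale. For a spot 10 units above the blank level, the spread of the blank spots alone gives a log2 ratio an SD of 0.41. The highest and lowest 5% were left out of that spread, so the SD over all blank spots is larger. The median of the miRNAs detected on both arrays was 14.5 units above the blank level.

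The procedure was tested on simulated data for 2019 probes. With signals as on the arrays and spill of light set from their brighter spots, the chosen setting called 5.88% of the detected miRNAs with a true log2 ratio of 1.5 in size. It called 11.6% of those at 2.0 and 2 of 47 unchanged ones. Without spill it called 9.09% and 11.5%. The blank-spot background called 78.0% and 96.5%, and 5 of 79 unchanged ones, with or without spill. The simulated foregrounds were built as the blank level plus signal, with spill in the local background only. The recovery of the blank-spot background was thus set by construction and does not rank the 2 backgrounds. In these simulations a low count of 2-fold differences under the chosen setting excludes few real ones.

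The named miRNAs were fixed by a rule: up to 12 of the largest increases and decreases at 2-fold (or 1.5-fold where fewer reached 2-fold), up to 5 per direction detected on 1 array only, the 10 with the highest mean signal, and up to 4 detected members of each list with the highest mean signal. The 22 lists were liver-enriched miRNAs, miR-103 and miR-107, let-7, the miR-17 cluster and paralogs, the miR-15 and miR-16 family, miR-30, the miR-23, miR-27 and miR-24 clusters, miR-29, miR-200, miR-34, miRNAs raised in cancer, C19MC, C14MC, markers of blood, endothelium, muscle, neurons and stroma and these together, miRNAs made without Drosha or Dicer, passenger strands, and miRNAs numbered 1200 and above. The median of a list with at least 2 detected members was set among 10000 random lists of the same size drawn within 10 bins of mean signal. miRNA names are those of the array, and host genes and neighbours were taken from the RefSeq gene table of assembly GRCh38.p14. Alternatives covered scaling, background, offset, detection and the deposited table.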

Results

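MicroRNAs (miRNAs) were measured in Huh7 cells, a human hepatocellular carcinoma line, cultured without apigenin or with this plant flavone at 10 µM for 24 h. The question, as the series describes it, was how the compound changed the levels of mature miRNAs. Total RNA labelled with the dye Hy5 was hybridised to 1-colour arrays, 1 for the control culture and 1 for the apigenin culture. There was therefore no spread between cultures to set a difference against, no p-value was computed, and every ratio given here describes this pair of arrays. Each array carried 2019 human miRNA probes, each spotted once, and most of these spots were as dim as the blank spots. The median miRNA foreground was 33.0 scanner units on both arrays, against a blank-spot mean of 32.6 (SD 1.95) on the control array and 32.5 (SD 2.08) on the apigenin array. These means and SDs leave out the highest and lowest 5% of the blank spots. After subtraction of the local background, 204 miRNAs were detected on the control array and 209 on the apigenin array, and 5.25% of the usable probes were detected on both. Some of these may be no brighter than empty spots, whose share above this limit was not computed. A limit set likewise on the foreground was passed by 6.27% of the blank spots on the control array and 8.43% on the apigenin array. miR-4454 alone carried 64.4% of the summed miRNA signal of the control array and 56.9% of that of the apigenin array.

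miR-4286, miR-1260a, miR-1260b and miR-1246 were brighter on the apigenin array, and miR-17-5p, a member of the oncogenic cluster transcribed from MIR17HG, was dimmer. In the chosen setting miR-4286 was 2.91-fold higher with apigenin, a log2 ratio of 1.54 that was 0.10 in the lowest of 12 other settings. miR-1260a was 2.07-fold higher, miR-1260b 1.57-fold and miR-1246, a short RNA that matches part of the U2 spliceosomal RNA, 1.55-fold. miR-17-5p had a log2 ratio of −0.40 and a foreground of 196 units without and 120 units with apigenin. These 5 miRNAs kept their direction in all 12 other settings of background and scaling, as did miR-4723-5p, miR-4497 and miR-106b-5p, all higher with apigenin, out of the 33 miRNAs detected on both arrays that a fixed rule named. Several of these settings differ only by a shift common to all miRNAs, and all rest on the same spots. Keeping a direction across them is therefore not independent support. miR-3960 was 1.54-fold higher but had a log2 ratio of −0.13 when the arrays were scaled on the second of the 2 spike-in controls.

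The sizes of these differences depended on the background and the scaling together. With the level of the blank spots as background and quantile normalization kept, the log2 ratio of miR-4286 was 0.10 in place of 1.54, that of miR-1260a 0.45 in place of 1.05 and that of miR-3960 0.25 in place of 0.63, while miR-1260b stood at 0.70 against 0.65 and miR-1246 at 0.89 against 0.64. With the arrays then scaled on all their spike-in spots in place of quantile normalization, the ratio was 0.42 for miR-4286, 0.49 for miR-1260a, 0.36 for miR-1260b, 0.54 for miR-1246 and 0.01 for miR-3960. miR-17-5p had a log2 ratio of −0.85 with the blank-spot background after quantile normalization and −1.13 on the spike-in scale. miR-4497 had a log2 ratio of 0.01 after quantile normalization although its foreground was 370 units with apigenin and lower without, and its ratio was 1.02 with the unscaled blank-spot background and 0.79 on the spike-in scale. For comparison, the 16 spots named as spike-in controls, for which the amounts added are not given in the sources used here, had log2 ratios with an SD of 0.71 under the local background and of 0.31 under the blank-spot background. Both SDs were taken before normalization between the arrays. They describe bright spots, with a median foreground of 2229 units on the control array and 2621.5 on the apigenin array. The spike-in controls differed from each other, with a mean log2 ratio of 0.08 (SE 0.045, 8 spots) for the first and 0.37 (SE 0.13, 8 spots) for the second under the blank-spot background. Scaled on the first alone, miR-4286 had a ratio of 0.56, and scaled on the second alone 0.27, which is below the spread of the spike-in spots. miR-1260b fell below that spread on the second spike-in too, at 0.22, while miR-1260a stood at 0.35, miR-1246 at 0.40 and miR-17-5p at −1.27. That spread, 0.31, is over all 16 spots. The 8 spots of the second spike-in alone had an SD of 0.37, which miR-1260a did not reach and miR-1246 barely exceeded. In the chosen setting the differences of miR-4286 and miR-1260a exceeded 1 SD of the spike-in spots, and those of miR-1260b, miR-1246, miR-3960 and miR-17-5p did not.

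**Figure D1:**
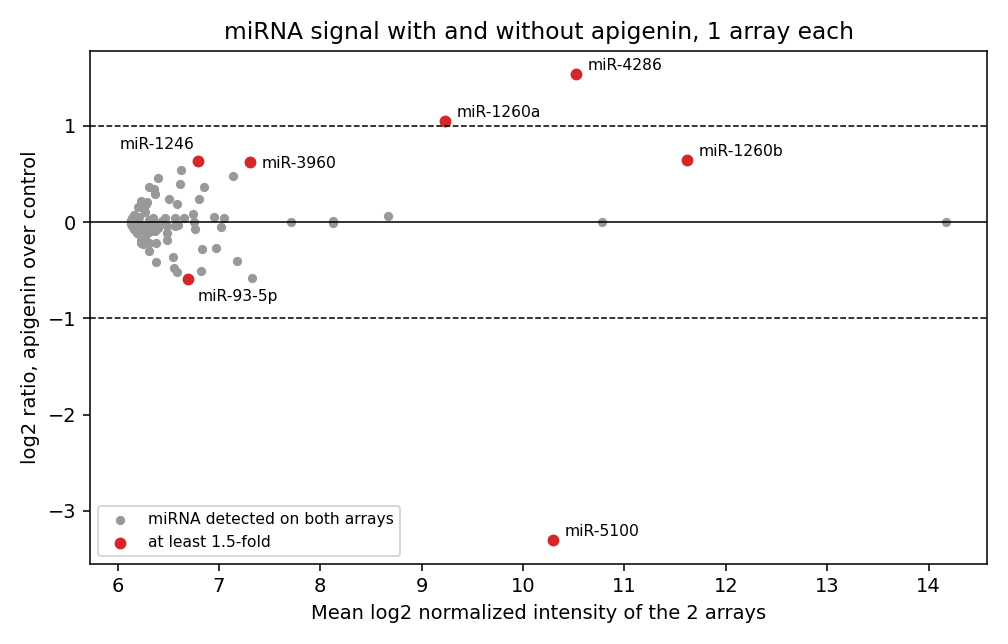
Log2 ratio of apigenin over control for the miRNAs detected on both arrays (vertical axis) against the mean log2 normalized intensity of the 2 arrays (horizontal axis), with local background and quantile normalization. Each point is 1 miRNA, red points differ by at least 1.5-fold, dashed lines mark 2-fold, and most miRNAs lie at low intensity near 0 while miR-5100 lies at −3.31.

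Across the miRNAs detected on both arrays, 2 (miR-4286 and miR-1260a) were at least 2-fold higher with apigenin and 1 (miR-5100) was at least 2-fold lower. At 1.5-fold, 5 were higher and 2 were lower, the second of these being miR-93-5p. The log2 ratio of miR-5100 was −3.31 and that of miR-93-5p was −0.59. miR-5100 was below 0 in 7 of the 12 other settings and miR-93-5p in 9. The foreground of miR-5100 was 5215 units without and 6569 units with apigenin, while its local background was 2025 and 6047 units, and its log2 ratio was −3.80 with plain local subtraction, −0.43 with the blank-spot background after quantile normalization and 0.11 on the spike-in scale. The foreground of miR-93-5p was 115 and 119 units, its local background 34 and 89 units, and its ratio −0.16 on the spike-in scale and 0.07 with the blank-spot background unscaled. Of the miRNAs detected on both arrays, 46.2% had a ratio above 0, against 32.1% with no normalization between the arrays and 30.2% after scaling to the 75th percentile. In the authors' deposited value table, 75.8% of the 260 miRNAs listed for both arrays had a ratio above 0, with 25 at least 2-fold higher and 1 at least 2-fold lower, and the median log2 ratio was 0.29. With that median set to 0, the table held 10 at least 2-fold higher and 5 at least 2-fold lower. The spike-in scale lowered every unscaled blank-spot ratio by 0.23. This put the median of all 216 miRNAs detected by foreground on both arrays at −0.15. Before normalization the median log2 ratio of the miRNAs detected on both arrays was −0.14.

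The brightest miRNAs other than those above differed little after quantile normalization. The ratios of miR-4454, miR-4284 and miR-6089 were 0.00 because each held the same rank on both arrays, and those of miR-4723-5p and miR-1273g-3p were 0.07 and −0.01. With median scaling in place of quantile normalization, miR-4723-5p had a log2 ratio of 1.23, miR-4284 0.98, miR-1273g-3p 0.98, miR-6089 0.34 and miR-4454 −0.11. On the spike-in scale miR-4284 had a log2 ratio of 0.43, miR-6089 0.34, miR-4723-5p 0.21, miR-1273g-3p 0.00 and miR-4454 −0.25.

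Among liver-enriched miRNAs, 3 of 10 probes were detected on both arrays, and none differed by 1.5-fold. miR-122-5p, the dominant miRNA of hepatocytes, had a foreground of 290 units without and 284 units with apigenin. Its log2 ratio was −0.58 with the local background and −0.26 on the spike-in scale, and it was −0.18 in the deposited table with its median set to 0. miR-192-5p, at 80 units on both arrays, had a log2 ratio of −0.22, and miR-194-5p, whose precursor MIR194-2 neighbours MIR192, had a ratio of 0.05 that was −0.19 on the spike-in scale. The median of the 3 was −0.22, at percentile 5.28 of 10000 random lists matched on signal, and it was −0.10 in the deposited table with its median set to 0. With the unscaled blank-spot background the median of 4 members was −0.01, at percentile 41.4.

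Both detected members of the miR-103 and miR-107 group, which regulates insulin sensitivity in liver, had ratios below 0 with the local background and quantile normalization, but miR-107 stood at 0.12 after median scaling and at 0.01 with no normalization. miR-103a-3p had a log2 ratio of −0.37 and miR-107 of −0.07, a median of −0.22 at percentile 16.4. The foreground of miR-103a-3p was 156 units without and 176 units with apigenin and that of miR-107 was 131 and 108 units, so that with the blank-spot background their ratios were 0.22 and −0.38.

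In the miR-17 cluster and its paralogs, which promote proliferation, 12 of 30 probes were detected on both arrays, 8 with ratios below 0 and 3 above. Their median log2 ratio was −0.07, at percentile 6.04, and it was −0.12 in the deposited table with its median set to 0 and 0.01 with the unscaled blank-spot background over 13 members, 6 below 0 and 7 above. miR-20a-5p, encoded beside miR-17-5p in MIR17HG, had a ratio of −0.50 with the local background and −0.31 on the spike-in scale. Its foreground was 121 units without and 116 units with apigenin, its local background 29 and 73 units. With the unscaled blank-spot background the ratio of miR-20a-5p was −0.08. miR-106a-5p, of the paralogous cluster in MIR106AHG, had a ratio of 0.05 that was −0.10 on the spike-in scale. miR-106b-5p, encoded with miR-93-5p and miR-25, was 0.08 and 0.22. miR-20b-5p, also of the MIR106AHG cluster and detected on both arrays, was not among the miRNAs named by the rule. Its ratio was −0.52 with the local background, below the −0.40 of miR-17-5p, and −0.59 in the deposited table before centring. With the unscaled blank-spot background the ratio of miR-20b-5p was also below 0. miR-16-5p, the single member of the miR-15 and miR-16 family detected above the local background on both arrays (3 by foreground), had a ratio of −0.27, against −0.29 in the deposited table with its median set to 0.

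Of the clusters of miR-23, miR-27 and miR-24, 5 of 11 probes were detected on both arrays, with a median of −0.09 at percentile 9.16 that was −0.28 in the deposited table with its median set to 0. miR-23a-3p, miR-23b-3p and miR-24-3p had ratios of −0.11, −0.09 and −0.12, and miR-27b-3p of 0.05 that turned to −0.41 on the spike-in scale. In the miR-30 family, miR-30b-5p and miR-30c-5p both had a ratio of −0.06, a median at percentile 34.7 that was −0.22 in the deposited table with its median set to 0. Among miRNAs often raised in cancer, miR-21-5p had a ratio of 0.01 and miR-221-3p of −0.01, with a list median of 0.00 at percentile 59.0. On the spike-in scale miR-21-5p stood at 0.13 and miR-221-3p at −0.49, and the unscaled median of the 4 members detected by foreground was −0.18, at percentile 17.6. miR-487b, the single miRNA of the imprinted C14MC cluster detected above the local background on both arrays (2 by foreground, with an unscaled median of 0.81 at percentile 98.3), had a ratio of 0.04, with foregrounds of 44 and 56 units, and of 0.82 on the spike-in scale. miR-320a, made without Drosha cleavage, had a ratio of −0.07 that was 0.02 on the spike-in scale.

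miRNAs numbered 1200 and above made up 57 of those detected on both arrays, with 35 above 0 and 19 below and a median log2 ratio of 0.04, against −0.04 for the other 49. This median lay at percentile 99.995 of random lists matched on signal, and at percentile 94.7 with the blank-spot background after quantile normalization. The difference between the medians of the 2 groups was 0.08, and with the blank-spot background it was 0.19 under every spike-in scaling, since such a scaling moves all miRNAs alike. With detection above the local background, no member of the let-7, miR-29, miR-200, miR-34 or C19MC lists was detected on both arrays, while by foreground 4 let-7 members, 1 of miR-29 and 1 of C19MC were. Of the 41 probes for markers of blood cells, endothelium, muscle, neurons and stroma, none was detected on both arrays above the local background and 3 were by foreground, 1 each of blood cells, neurons and stroma. No probe was named as a passenger strand with a star.

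A further 5.10% of the probes were detected on the apigenin array only and 4.86% (98 miRNAs) on the control array only, in the chosen setting. The share of blank spots above this limit was not computed. Above the foreground limit lay 6.27% of the blank spots on the control array and 8.43% on the apigenin array. Detection on 1 array only therefore does not show that a miRNA was present there. miR-4417 was at least 1.27-fold higher with apigenin and miR-296-5p and miR-4502 at least 1.23-fold. miR-3178 was at least 1.13-fold higher on the control array, miR-30d-5p and miR-15b-5p at least 1.11-fold and miR-6724-5p at least 1.10-fold. For miR-6724-5p the foregrounds were 57 units without and 52 units with apigenin, and the local backgrounds 35 and 50 units. All these bounds rest on 1 spot per array and lie within 1 SD of the spike-in log2 ratios (0.71). That SD describes bright spots before normalization, so it gives no spread for dim spots such as these. The rule also named miR-1234-5p and miR-1237-5p on the apigenin array and miR-3651 on the control array, but their bounds rested on the local background and are not given as folds. Their foregrounds without and with apigenin were 76 and 74 units, 65 and 63 units, and 64 and 62 units, with unscaled blank-spot log2 ratios of −0.06, −0.08 and −0.09.

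**Figure D2:**
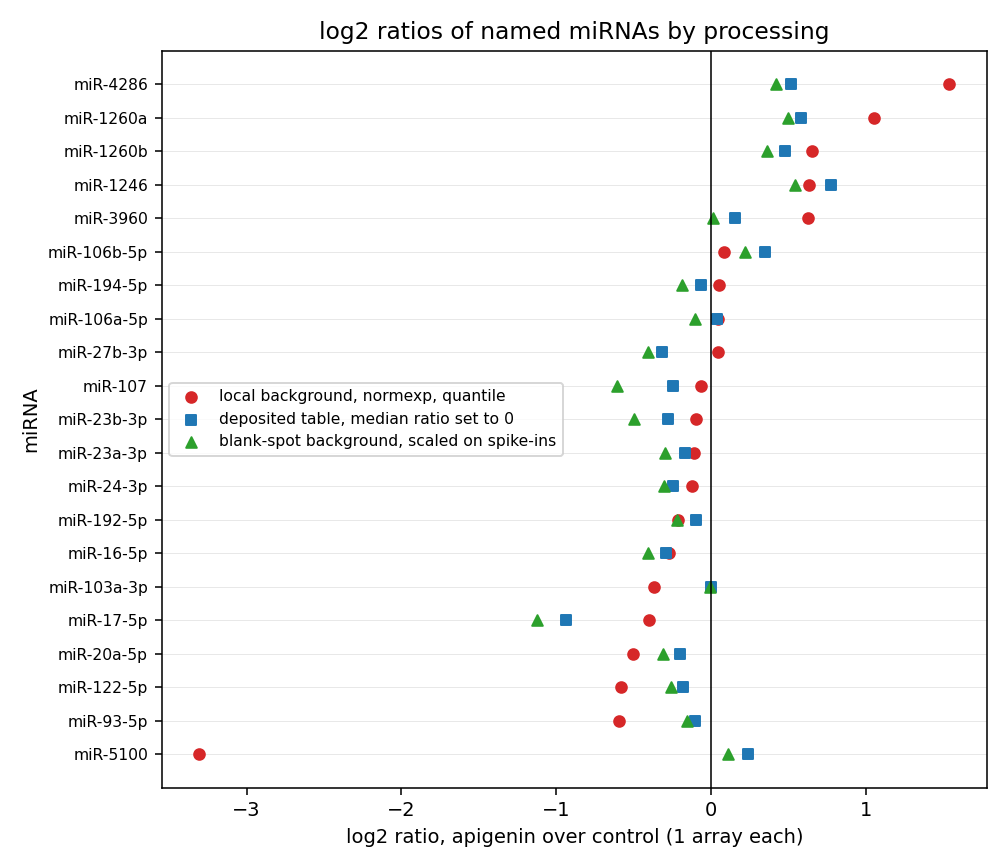
Log2 ratio of apigenin over control (horizontal axis) of miRNAs named in the text (vertical axis) from 1 array per group, with local background and quantile normalization (circles), in the deposited table with its median ratio set to 0 (squares), and with the blank-spot background scaled on the spike-in spots (triangles). miR-4286 lies to the right of 0 in all of them, from 0.42 to 1.54 (0.10 in a setting not drawn, the blank-spot background with quantile normalization), and miR-17-5p to the left, from −1.13 to −0.40, while miR-5100 lies at −3.31 and at 0.24 and 0.11.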

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

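The spots named S-Probe, whose target is not given in the sources used here, were set against the blank spots only after their values were seen. Outside the miRNA comparison, 7 of them stood above the blank-spot limit (36.6 units on the apigenin array) on both arrays, 3 with a higher and 4 with a lower value on the apigenin array. S-Probe1014 read 742 units with apigenin and had a log2 ratio over control of 0.62 above the blank level. S-Probe1002 read 84 units with apigenin and 77 without, and S-Probe1008 read 50 and 46. Of the lower ones, S-Probe1013 read 78 units with apigenin and 89 without, S-Probe1006 39 and 41, S-Probe1007 39 and 40, and S-Probe1009 39 and 42. No explanation was tested.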

How the results depend on the processing

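The blank-spot backgrounds, the deposited table with its median set to 0 and detection on the foreground were chosen after seeing the data, the other alternatives before. The number of miRNAs at least 2-fold higher, 2 in the report, was 4 after scaling to the median, 4 after scaling to the 75th percentile, 4 without scaling, 7 with plain local subtraction, 6 with normexp at offset 0, 25 in the deposited table and 10 with that table centred. With the blank-spot background it was 10 after quantile normalization, 13 unscaled, 4 on the spike-in scale and, scaled on the first or second spike-in alone, 9 and 3. The number at least 2-fold lower, 1 in the report, was 12 with local subtraction, 5 at offset 0, 5 in the centred table, and 7, 5, 7, 5 and 14 for the same blank-spot settings. Of the usable probes, 10.1% were detected on the control and 10.4% on the apigenin array in the report, 5.25% and 5.85% at 3 SD, 1.29% and 0.991% against the spread of the local background, and 15.6% and 18.7% on the foreground. The median log2 ratio before normalization was 0.076 with the blank-spot background in place of −0.14. It was −0.072 with local subtraction and 0.027 over the brighter detected miRNAs, and the spike-in spots had a mean of −0.010. With local subtraction the list medians were −0.94 for liver-enriched miRNAs, −0.43 for the miR-17 cluster and paralogs and −0.46 for the miR-23, miR-27 and miR-24 clusters. The miR-17 list stood at −0.40 over the brighter detected miRNAs and at 0.16 in the deposited table, or −0.12 with that table centred. Scaled on the second spike-in it stood at −0.36 and the miR-23, miR-27 and miR-24 clusters at −0.47. The list numbered 1200 and above stood at 0.41 in the deposited table, 0.14 with the blank-spot background, 0.23 with it unscaled, and 0.15 and −0.14 scaled on the first and second spike-in. The spike-in scalings move all miRNAs alike, and the list's median stayed 0.19 above that of the others in each of them and unscaled, and 0.24 above in the deposited table, centred or not. This difference was 0.10 with the blank-spot background after quantile normalization, 0.36 with local subtraction and 0.00 with no detection filter. miR-3960 reversed to −0.13 scaled on the second spike-in. miR-5100 reversed to 0.53 in the deposited table, 0.24 in the centred table, 0.33 with the unscaled blank-spot background, 0.11 on the spike-in scale and 0.25 scaled on the first spike-in. miR-93-5p reversed to 0.18 in the deposited table (−0.10 with it centred), 0.054 with the blank-spot background and 0.071 with it unscaled. For miR-5100 the values could not decide the cause, and for the others the cause was not tested. Among the single miRNAs, 173 values under planned and 174 under added settings moved by less than 1 SD of the spike-in ratios (0.71), and 25 and 24 moved by more, with reversals counted by their size on either side. That SD describes bright spots before normalization, so a move within it does not show that the value of a dim miRNA is stable. No paired analysis was possible because each group had 1 array. Leaving out a replicate, taking the median of spots and counting any passing spot were not run, since each group had 1 array and each probe 1 spot. Signal over background limited the ratios as well, since the median of the miRNAs detected by foreground lay 14.5 units above the blank level.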

Other observations

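With the blank-spot background, which added miRNAs to those detected on both arrays, the values described here were chosen after they were seen. All 4 detected members of the miR-30 family had unscaled log2 ratios below 0, with a median of −0.41 at percentile 1.93 of random lists matched on signal. miR-30d-5p had a ratio of −0.70, with foregrounds of 66 units without and 53 units with apigenin, miR-30c-1-3p of −0.49, miR-30c-5p of −0.33 and miR-30b-5p of −0.32. The 5 members of the miR-23, miR-27 and miR-24 clusters had unscaled ratios from −0.27 for miR-23b-3p to −0.07 for miR-23a-3p. Their median of −0.10 lay at percentile 21.02, and after quantile normalization miR-23a-3p stood at 0.09 and miR-24-3p at 0.08. Of the miR-15 and miR-16 family, miR-15b-5p had a ratio of −0.49 and miR-16-5p of −0.18, while miR-15a-5p, near the limit at 39 and 46 units, had 1.09. The 4 let-7 members had a median of 0.21 that became −0.01 on the spike-in scale.

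miR-210, the miRNA most directly induced by hypoxia, had foregrounds of 51 units without and 41 units with apigenin, a ratio of −1.11 unscaled and −1.33 on the spike-in scale. miR-1915-3p, at 50 and 39 units, had the lowest unscaled ratio of the 216 miRNAs detected in this way, −1.41. The highest were those of miR-4496 at 1.92, miR-4667-5p at 1.67 and miR-4281 at 1.63, all at 40 units or less without apigenin. These spots were close to the blank level on at least 1 array, and the spread of empty spots alone gives a ratio an SD of at least 0.41 at 10 units.

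For the next patterns, the percentile of the miRNAs numbered 1200 and above in the chosen setting was planned, and the tests of print position and of apigenin treatment for these miRNAs were chosen before their results were seen. The other tests were chosen after. miR-5100 had a log2 ratio of −3.31 with the local background. With the blank spots as background and quantile normalization the ratio was −0.43, and on the spike-in scale it was 0.11 with a spike-in SD of 0.31. Both values leave the local background out, so they cannot show whether the light around the spot also lay under it. A lower level in the treated culture therefore stays open. A candidate explanation for the value of −3.31 is light of the spot counted in its local background, which was 2025 units without and 6047 units with apigenin.

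miRNAs numbered 1200 and above had unscaled blank-spot ratios with a median of 0.23, against 0.04 for the others. Among random lists of matched brightness their median lay at percentile 97.53, and at 99.995 in the chosen setting. It lay above the central 95% of random lists in 7 of 8 settings, and at 94.7 with the blank-spot background after quantile normalization. These settings share the same spots and are not independent. The unscaled blank-spot value lay at the edge of the central 95% (97.75 in another draw of lists). Within quartiles of brightness, the unscaled difference of medians was −0.02 in the dimmest, then 0.14 and 0.19, and 0.225 in the brightest. The difference was thus absent in the dimmest quartile and present within the brighter ones, where brightness between quartiles cannot account for it. Brightness within a quartile was not matched. Since the matched percentile was also 94.7 with the blank-spot background after quantile normalization, brightness stays open. The difference of medians lay at percentile 91.4 of shuffles within print blocks, and at 93.5 in the chosen setting, so that print position stays open. An effect of apigenin may also account for it and cannot be told apart from an effect of the array, because there was 1 pair of arrays.

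By foreground, 378 miRNAs were detected on the apigenin array and 315 on the control array. Of the blank spots, 8.43% on the apigenin array and 6.27% on the control array lay above the same limits. Raising the control array's signal by the mean spike-in ratio brought its number to 31 above that of the apigenin array, within counting error (49.3). Foregrounds are whole units, so the number moves in large steps (raising it by the first spike-in alone left it at 315), and this test is too coarse to decide whether brighter labelling or the higher detector gain may account for the excess of 63. The blank spots above the limit, scaled to the number of miRNA probes, gave an excess of 43.6 (95% interval −4.32 to 91.6), which leaves a wider spread of empty spots open. An effect of apigenin on the number of detected miRNAs was not tested, since each group had 1 array.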
